A study of Mus musculus with 4 samples.

How the data were processed

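Live CD45+ cells sorted from mouse liver were profiled as 4 libraries, 2 from wild-type (WT) mice and 2 from mice with a myeloid-specific HIF-2a knock-out (KO), all on the steatohepatitis diet. The deposited matrices hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 5.0.1 on mm10. The deposited barcode and feature lists are text of another unit than counts, namely the cell barcodes and the gene identifiers and symbols. Every barcode had at least 500 UMIs. The annotation release is not stated, and 99.6% of the genes were found in the annotation used for positions.

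Cells with at least 500 UMIs, at least 200 genes and under 15% mitochondrial UMIs were kept. Doublets were removed per library with the Scrublet method of scanpy 1.11.5, which took 3542 and 3857 barcodes from WT replicates 1 and 2 and 4522 and 4572 from KO replicates 1 and 2. All libraries were clustered together on log-normalized counts, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2), without group or library as input. Clusters were named from fixed markers of 21 cell types, and a named class is called "-like" since no other measurement of cell type exists. Clusters whose markers decided for no type kept a number.

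UMI counts were summed per library and class. KO was compared with WT by the quasi-likelihood test of edgeR 4.0.16, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment within a class at 0.05. The 4 myeloid classes came first, and 8 lymphoid and dendritic classes were tested beside them. Of these only the lymphoid classes stand for cells outside the described deletion. Cell numbers per class were tested with edgeR with the kept cells of a library as offset. The difference of the KO effect between Kupffer-like and recruited macrophage-like cells was tested as an interaction in edgeR with library as block. The 30 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. No list kept its call with an estimated correlation. In the 4 myeloid classes fry called 2, fibrosis and matrix factors in Kupffer-like cells (adjusted p = 0.04) and NF-kB genes in monocyte-like cells (adjusted p = 0.00389). Log2 fold changes are KO minus WT, ± is SD or, where stated, the standard error, and CPM are counts scaled to the library total after TMM unless stated otherwise.

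Filters, classes, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took Epas1, Hif1a and Lyz2, then up to 10 genes per direction with the largest change among those called, at 20 CPM or more in either group and with both KO libraries beyond both WT libraries (3 per direction in lymphoid and dendritic classes), and up to 4 genes per list with the smallest p. Receptor V segments, haemoglobins, mitochondrial, Xist and Y-linked genes were left out of the 10. In a test on simulated data, with 100 genes changed by log2 1 and 100 by log2 2, edgeR recovered 88, 94, 93 and 79 of the first and 98, 100, 100 and 100 of the second in Kupffer-like, recruited macrophage-like, monocyte-like and neutrophil-like cells, and 3.63%, 2.02%, 6.31% and 1.65% of all simulated calls were false. The changed genes were taken from those above a minimum expected count. Counts were drawn for each gene independently at the trended dispersion, without library effects other than size. These rates thus need not hold for the real data.

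The alternatives were DESeq2 1.42.0, RLE normalization, no filter or a stricter one, other doublet, UMI and mitochondrial limits, Leiden resolution 2, equal cells or counts per library, a replicate block, adjustment over all classes, omission of genes of other cell types, and leaving out each library. With 1 library left in a group, its spread is assumed to be that of the other group. Replicate numbers are not stated to pair the samples. Depth was 108553153 to 151843547 UMIs per library.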

Results

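The series profiled sorted live CD45+ leukocytes from the liver of C57BL6 mice of about 8 months by droplet single-cell RNA sequencing of 3' ends. The mice were fed a high-fat, high-cholesterol diet that induces nonalcoholic steatohepatitis (NASH). The comparison was between wild-type (WT) mice and mice with a knock-out (KO) of HIF-2a in myeloid cells, with 2 libraries in each group. HIF-2a, encoded by Epas1, is an oxygen-regulated transcription factor. The libraries held 39748 and 36961 barcodes (WT replicates 1 and 2) and 43975 and 44949 barcodes (KO replicates 1 and 2), with 108553153, 127898459, 151843547 and 142632908 UMIs. After filtering, 35748, 32713, 38737 and 40232 cells remained, with median counts of 2104, 2584, 2639 and 2333 UMIs per cell. The labels do not say that the libraries come from separate animals, so p-values of single genes and of shares measure only the spread between these samples. Those of camera compare the genes of a list with the other genes. At the preset correlation they are no measure of the spread between libraries, however small they are.

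The deleted gene itself was barely detected in myeloid cells, and its 3' signal was not lower in the KO. Epas1 (ENSMUSG00000024140, chromosome 17 of mm10, from 86753700) stood at 8.61, 9.63, 11.97 and 8.13 CPM (counts scaled to the depth of the library) in Kupffer-like cells of WT replicates 1 and 2 and KO replicates 1 and 2. In recruited macrophage-like cells it stood at 8.11, 6.85, 7.99 and 9.19 CPM, in monocyte-like cells at 6.34, 6.73, 8.40 and 7.23 CPM, and in neutrophil-like cells at 12.2, 10.4, 10.2 and 14.98 CPM. The log2 fold changes (KO minus WT) were 0.15, 0.19, 0.26 and 0.17, none past the test (adjusted p = 0.783, 0.647, 0.547 and 0.826). The share of Kupffer-like cells with an Epas1 UMI was 2.85%, 4.90%, 5.51% and 3.81%, against 1.96%, 2.50%, 2.30% and 4.57% of T cell-like cells, with median depths of 3428, 5493, 4710 and 4685 UMIs against 1005, 1173, 1360 and 1126 UMIs. With every cell thinned to 1000 UMIs the shares were 0.866%, 1.03%, 1.13% and 0.655% of Kupffer-like cells and 1.65%, 2.12%, 1.51% and 3.73% of T cell-like cells. Thinning lowers UMIs from free RNA as well, so these shares do not tell expression from free RNA. The liver endothelial cell-like cells that had passed the CD45+ sort held an Epas1 UMI in 59.3%, 70.0%, 72.9% and 66.6% of cells. A 3' tag can lie outside a deleted exon, so these counts do not measure the deletion. Hif1a, which encodes the related HIF-1a, differed by log2 0.06, 0.24, 0.02 and 0.00 in the same 4 classes, and no class passed the test.

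Lyz2, the lysozyme gene at which the Cre recombinase of many myeloid knock-outs is inserted, was lower in both KO libraries, but to different depths. In monocyte-like cells it fell from 10470 and 11850 CPM in the WT libraries to 5526 CPM in KO replicate 1 and 23.6 CPM in KO replicate 2, as normalized CPM. Recruited macrophage-like cells held 7977 and 8543 against 3034 and 11.3 CPM, Kupffer-like cells 4783 and 4661 against 2151 and 38.6 CPM, and neutrophil-like cells 4108 and 4288 against 1886 and 21.5 CPM. The labels do not name the Cre driver. Because the KO libraries lay far apart, the edgeR test did not call Lyz2 (log2 -2.01, -2.44, -2.11 and -2.14 in the 4 classes, adjusted p = 0.577, 0.402, 0.439 and 0.501). Without KO replicate 1 or without KO replicate 2 it was called in all 4 classes, with log2 -8.88 and -1.02 in monocyte-like cells. Lyz1, the neighbouring lysozyme gene on chromosome 10, rose in the KO, with log2 3.53 in monocyte-like cells (18.2 and 25.2 against 206 and 296 CPM), 2.81 in Kupffer-like cells, 2.34 in recruited macrophage-like cells and 3.37 in neutrophil-like cells.

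**Figure D1:**
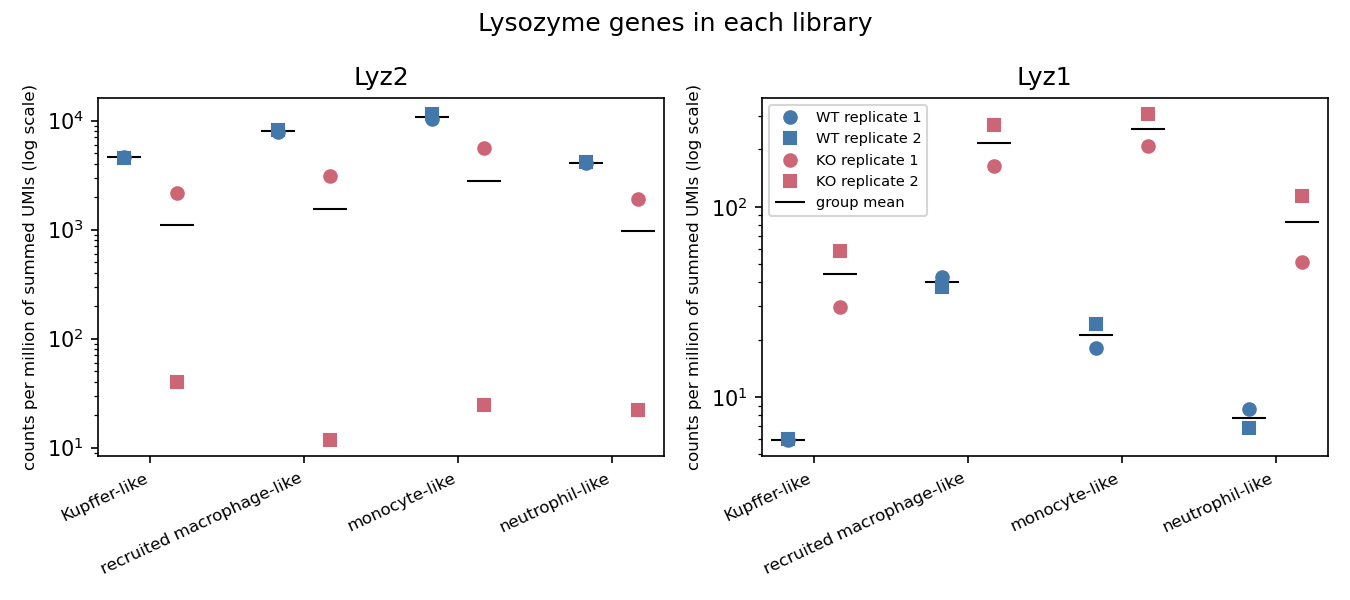
Lyz2 (left) and Lyz1 (right) in the 4 myeloid classes, in CPM of summed UMIs without TMM on a log axis, with 1 point per library and a dash for the group mean. In KO replicate 2 Lyz2 lay at 11.7 to 39.8 CPM, while KO replicate 1 held 1902 to 5576 CPM.

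The first comparison asked whether the balance of resident and recruited macrophages differed, since monocyte-derived cells replace resident Kupffer cells in steatohepatitis. Kupffer-like cells made up 9.88% ± 1.98 (SD, n = 2) of the sorted CD45+ cells in the KO and 5.74% ± 1.32 (SD, n = 2) in the WT. Recruited macrophage-like cells made up 6.88% ± 1.84 (SD, n = 2) in the KO and 11.7% ± 0.261 (SD, n = 2) in the WT. Both KO libraries lay beyond both WT libraries for either class. Cluster 4, with macrophage and T cell genes among its leading genes, was placed in no class. It scored highest for recruited macrophages and went the other way, at 5.75% in the KO and 3.86% in the WT (log2 0.58, edgeR adjusted p = 0.144). The size of the recruited macrophage-like difference thus depends on where the cells of cluster 4 belong. They held a median of 3926 UMIs, against 3278 in the recruited macrophage-like class and 1080 and 1180 in T cell-like clusters 0 and 2. Remaining doublets of macrophages and T cells are not excluded. Among dendritic cells, cDC2-like cells, which present antigen to CD4 T cells, made up 3.75% ± 0.145 (SD, n = 2) in the KO and 7.69% ± 0.363 (SD, n = 2) in the WT. NK cell-like cells made up 4.48% ± 1.24 (SD, n = 2) in the KO and 7.95% ± 1.89 (SD, n = 2) in the WT. Their log2 difference of -0.83 turned to 0.59 at Leiden resolution 2 and in a clustering without the called genes, chosen after the data were seen, where a cluster led by Klra6, Klra7 and Klra9 was named NK cell (edgeR adjusted p = 0.144, 0.294 and 0.28). A cluster without a name, led by the Ly49 receptor genes Klra6, Klra7 and Klra9 with Cd160 and Gzmb, held 12.4% and 3.73% of the KO libraries and 0.201% and 0.456% of the WT libraries.

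None of the 22 classes passed the edgeR test over all kept cells, while 4 had an unadjusted p under 0.05, namely cDC1-like (log2 -0.51), cDC2-like and recruited macrophage-like cells and the unnamed cluster. The log2 differences were 0.78 for Kupffer-like cells (adjusted p = 0.144), -0.76 for recruited macrophage-like cells (adjusted p = 0.144), -1.04 for cDC2-like cells (adjusted p = 0.0751, and 0.0291 at Leiden resolution 2) and 4.62 for the unnamed cluster (adjusted p = 0.0909). Counted only among macrophage-like and monocyte-like cells, the Kupffer-like share was 31.4% ± 2.43 in the KO and 19.5% ± 2.51 in the WT, which passed the test (log2 0.68, adjusted p = 0.00611). On the same base the recruited macrophage-like share was 21.8% ± 3.18 and 40.1% ± 3.25 (log2 -0.88, adjusted p = 0.00335), and the monocyte-like share did not pass (log2 0.22, adjusted p = 0.197). An exact two-sided permutation test of 2 libraries against 2 cannot go below 0.333, the value it gave for each of these classes. Shares are of cells that passed a CD45+ sort, so they do not count cells lost at the sort or at dissociation. The base of macrophage-like and monocyte-like cells leaves out cluster 4.

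**Figure D2:**
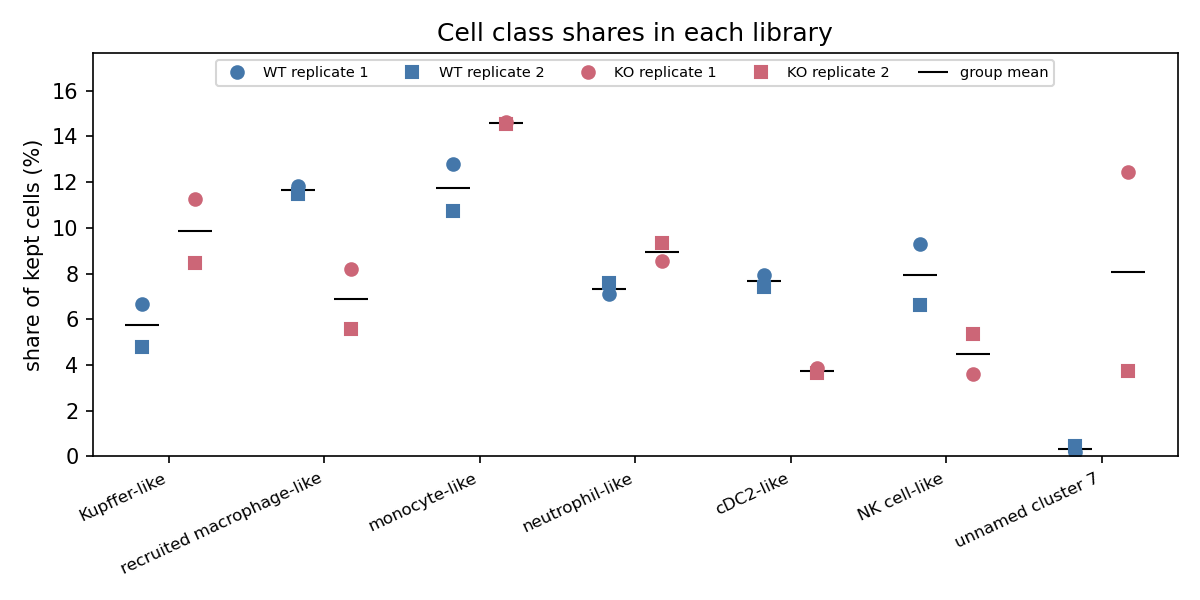
Share of the kept cells of each library (percent) in 6 named classes and 1 unnamed cluster, with 1 point per library and a dash for the group mean. Kupffer-like cells lay at 4.80% and 6.67% in the WT libraries and at 8.48% and 11.3% in the KO libraries.

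The next comparison asked which genes differed in resident macrophages. In KO Kupffer-like cells, Osm, Hbegf and immediate-early genes were lower, and Cxcl13 and 2 complement genes were higher. Osm was called in 9 and the complement gene Cfb in 11 of the 12 classes, so neither change is particular to Kupffer-like cells. Cxcl13, a chemokine that attracts B cells, rose by log2 3.47 ± 0.37 (SE), from 5.97 and 5.60 CPM to 42.2 and 86.5 CPM. The complement genes C4b and Cfb rose by log2 1.61 ± 0.10 and 1.41 ± 0.23 (SE). Thbs1 (thrombospondin, an activator of TGF-beta), Osm (oncostatin M, a cytokine of the IL-6 family) and Hbegf (an EGF receptor ligand) fell, with log2 -1.80, -1.73 and -1.27. Thbs1 is 1 of 9 genes of a 10 Mb window of chromosome 2 that changed alike in most cell classes, together with Gatm, Eif3j1, Spint1, Jmjd7, AA467197, Chp1, Kcnip3 and Dusp2. Of 33 NF-kB cytokine and chemokine genes 1 fell, Cxcl2 (log2 -0.85), 1 rose, and 14 passed when adjusted over the list alone, and the list was called downward (camera adjusted p = 2.16e-05; adjusted p = 0.238 with an estimated correlation). In all, 79 genes rose and 98 fell among 12501 tested.

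Further genes that rose most in Kupffer-like cells were Gatm, an enzyme of creatine synthesis (log2 1.74), Ly6a, a surface antigen induced by interferon (log2 1.60), Nudt16 (log2 1.39), Gzmb, a granule protease of cytotoxic lymphocytes (log2 1.56), and Eif3j2 (log2 5.20). Marco, a scavenger receptor, rose by log2 1.81 (51.1 and 49.6 against 214 and 138 CPM), but it is one of the genes by which the class was named. It was called in 6 of the 12 classes, with a median of log2 2.35 there. Atf3, Fosb and Jun, transcription factors of the immediate-early response, fell with log2 -1.52, -1.33 and -1.32. They were called in 12, 12 and 11 of the 12 classes. Gdf15, a stress cytokine, and Plk2, a kinase of the cell cycle, fell with log2 -1.49 and -1.28. Rpl29, a ribosomal protein gene (ENSMUSG00000048758, chromosome 9 from 106429454), fell by log2 3.14 and Eif3j1, a translation initiation factor (ENSMUSG00000027236, chromosome 2 from 122028546), by log2 2.51. The Kupffer-like class joined clusters 6, 13 and 25, of which cluster 13 held 85.1% and 80.2% in the WT and 79.9% and 76.7% in the KO libraries. The number of called genes was 91 without WT replicate 1, 527 without KO replicate 1 and 535 without KO replicate 2, against 177 with all libraries. Without WT replicate 1, 72 of the 177 calls were kept, and those of Cfb and Lyz1 were lost without either WT library.

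Genes of the lipid-associated macrophage program were lower in KO Kupffer-like cells. Of 30 measured members 6 fell and none rose, and 13 passed when adjusted over the list alone (camera adjusted p = 3.94e-15; adjusted p = 0.16 with an estimated correlation). The tetraspanins Cd9 and Cd63 fell with log2 -0.93 and -0.76, Gpnmb, a glycoprotein of lipid-laden macrophages, with log2 -0.96, and Mmp12, an elastase, with log2 -0.72. Gpnmb, Cd9, Fabp5 and Mmp12 are also markers by which recruited macrophage-like cells were named. That class was a smaller share of the KO libraries, and its RNA in Kupffer-like cells was not separated from a change within them. Cd9 was called in 7 of the 12 classes. Apoc1, an apolipoprotein, and Fabp5, a fatty acid carrier, fell with log2 -0.71 and -0.45. The calls of Fabp5 and Mmp12 were lost without WT replicate 2, where 101 of 177 calls were kept. Genes of fibrosis and matrix remodelling were lower as a group, with 7 of 31 down, 2 up and 17 passing when adjusted over the list alone (camera adjusted p = 3.98e-11; adjusted p = 0.16 with an estimated correlation).

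Interferon-response genes were higher in KO Kupffer-like cells. Of the 32 type I interferon genes 4 rose, none fell and 16 passed when adjusted over the list alone (camera adjusted p = 4.02e-10; adjusted p = 0.576 with an estimated correlation). Ifit1 and Irf7 rose with log2 0.67 and 0.60. Of the 28 interferon-gamma genes 2 rose, the GTPase genes Iigp1 (log2 1.03) and Gbp4 (log2 0.95), none fell and 17 passed when adjusted over the list alone (camera adjusted p = 8.36e-13; adjusted p = 0.44 with an estimated correlation). Of 36 immediate-early and heat shock genes, which also respond to tissue dissociation, 14 fell, none rose and 25 passed when adjusted over the list alone (camera adjusted p = 5.49e-35; adjusted p = 0.24 with an estimated correlation). Its 25 immediate-early members had a median log2 of -0.71, and its 11 heat shock members -0.21, which turned to 0.05 without WT replicate 1. The hypoxia and glycolysis list was not called in Kupffer-like cells (adjusted p = 0.477), with 1 of 36 members up, none down and 8 passing when adjusted over the list alone. Without WT replicate 1 the single-gene calls of Ifit1, Irf7, Iigp1 and Gbp4 were lost, as 72 of 177 calls were kept. The Kupffer cell identity list had 3 members up, 1 down and 7 passing when adjusted over the list alone (camera adjusted p = 0.0267; adjusted p = 0.577 with an estimated correlation), with Timd4, another naming marker, at log2 1.08 and Id1 at log2 -0.93. That call was lost without KO replicate 1 (adjusted p = 0.0993) and without WT replicate 1 (adjusted p = 0.195). The list's median of log2 0.07 in Kupffer-like cells was lower than in recruited macrophage-like, monocyte-like and neutrophil-like cells (0.21, 0.37 and 0.23), where 5, 7 and 3 members rose. It was lower too than in pDC-like and B cell-like cells, where 13 of 32 and 11 of 30 members rose (medians of 0.88 and 0.68). Markers of T or NK cells moved with the group too: 4 of 12 rose, none fell and 7 passed when adjusted over the list alone (camera adjusted p = 1.61e-11; adjusted p = 0.16 with an estimated correlation), among them Gzma (log2 1.10) and Ccl5 (log2 1.00).

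**Figure D3:**
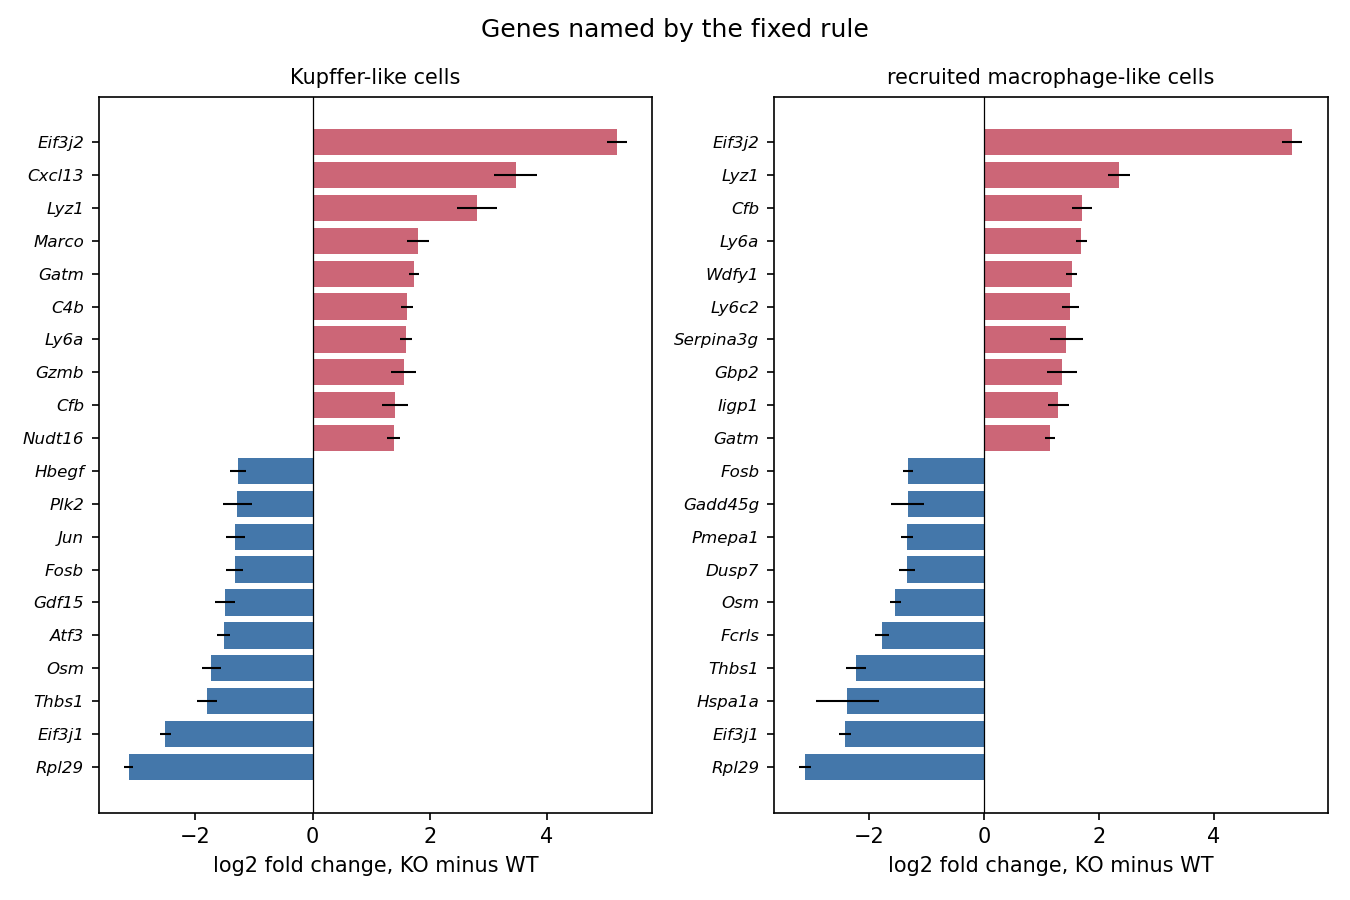
Log2 fold change (KO minus WT) with its standard error for the genes with the largest called changes in Kupffer-like (left) and recruited macrophage-like cells (right), 2 libraries per group. Eif3j2 and Rpl29 mark the ends in both classes, with log2 5.20 and -3.14 in Kupffer-like cells.

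The third comparison concerned macrophages recruited from blood. In KO recruited macrophage-like cells, the NF-kB and immediate-early lists were called downward and the interferon lists upward, though not with an estimated correlation. Thbs1, of the chromosome 2 window, fell by log2 2.23, from 109 and 155 CPM to 31.5 and 24.1 CPM, and Osm by log2 1.55. The chemokine genes Cxcl2 and Cxcl1, which attract neutrophils, fell with log2 -1.21 and -1.92. Cfb rose by log2 1.71 ± 0.18 (SE), Ly6c2, a monocyte surface antigen and naming marker of the monocyte-like class, by log2 1.496, and the interferon-induced Gbp2 and Iigp1 by log2 1.35 and 1.29. Cxcl2, Ly6c2, Gbp2 and Iigp1 were called in 8, 9, 8 and 7 of the 12 classes. In all, 169 genes rose and 199 fell among 12274 tested.

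Other genes that rose most were Ly6a (log2 1.69), Wdfy1 (log2 1.52), Serpina3g (log2 1.43), Gatm (log2 1.14) and Eif3j2 (log2 5.36). Fcrls, an Fc receptor-like gene of macrophages, fell with log2 -1.79, Dusp7, a MAP kinase phosphatase, with log2 -1.34, Pmepa1, a target of TGF-beta, with log2 -1.34 and Fosb with log2 -1.33. Rpl29 fell by log2 3.12 and Eif3j1 by log2 2.42. Hspa1a, a heat shock chaperone, fell with log2 -2.38, at 1196 CPM in WT replicate 1, 236 CPM in WT replicate 2, and 158 and 115 CPM in the KO libraries. Gadd45g, a stress-response gene, fell with log2 -1.34. All cells of the class came from cluster 12. The number of called genes was 160 without WT replicate 1 and 204 without WT replicate 2, against 368 with all libraries. Of the 368 calls 131 and 146 were kept, and those of Gbp2 and Serpina3g were lost without either WT library, those of Hspa1a and Gadd45g without WT replicate 1 and that of Iigp1 without WT replicate 2.

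In recruited macrophage-like cells 13 of 32 NF-kB cytokine and chemokine genes fell, none rose and 18 passed when adjusted over the list alone (camera adjusted p = 1.28e-13; adjusted p = 0.352 with an estimated correlation). Nfkbiz, a regulator of NF-kB targets, fell with log2 -0.76. Of 32 type I interferon genes 12 rose, none fell and 22 passed when adjusted over the list alone (camera adjusted p = 6.8e-21; adjusted p = 0.554 with an estimated correlation), with Irf7 at log2 0.78, Ifi47 at log2 0.83 and Ifit2 at log2 0.71. Of 28 interferon-gamma genes 9 rose, none fell and 19 passed when adjusted over the list alone (camera adjusted p = 1.3e-16; adjusted p = 0.554 with an estimated correlation). Of 36 immediate-early and heat shock genes 20 fell, none rose and 25 passed when adjusted over the list alone (camera adjusted p = 1.94e-38; adjusted p = 0.352 with an estimated correlation). The fibrosis and matrix list had 8 of 30 members down, 2 up and 15 passing when adjusted over the list alone (camera adjusted p = 5.16e-06; adjusted p = 0.554 with an estimated correlation). Casp4, an inflammatory caspase, fell with log2 -1.17. Casp4 and Nfkbiz were each called in 8 of the 12 classes. The calls of Ifi47 and Ifit2 were lost without WT replicate 2, where 146 of 368 calls were kept. The median log2 of the 11 heat shock members was -0.18 and turned to 0.26 without WT replicate 1. Markers of liver endothelial cells were higher as well, with 3 of 10 up, none down and 4 passing when adjusted over the list alone (camera adjusted p = 4.47e-04; adjusted p = 0.559 with an estimated correlation). So were hepatocyte and T or NK cell markers, with 4 of 22 and 1 of 12 up, none down, and 10 and 1 passing when adjusted over the list alone (camera adjusted p = 5.36e-06 and 3.61e-04; adjusted p = 0.758 and 0.611 with an estimated correlation). The hepatocyte call was lost without KO replicate 1 (adjusted p = 0.734) and the T or NK cell call without KO replicate 2 (adjusted p = 0.157).

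Lipid-handling genes of recruited macrophage-like cells went both ways. Of 30 lipid-associated macrophage genes 5 fell, 1 rose and 10 passed when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0974). Trem2, a lipid-sensing receptor, fell with log2 -0.57, Apoe with log2 -0.52, Cd9 with log2 -0.73 and Syngr1 with log2 -0.76. Trem2 and Cd9 were called in 8 and 7 of the 12 classes. Cd36, a fatty acid and lipoprotein receptor, and Nr1h3, the sterol-sensing receptor LXR-alpha, rose with log2 0.45 and 0.55. The hypoxia and glycolysis list was called upward, with 2 of 37 members up, 1 down and 19 passing when adjusted over the list alone (camera adjusted p = 2.83e-04; adjusted p = 0.712 with an estimated correlation). Pgk1, a glycolytic enzyme, and Slc16a3, a lactate exporter, rose with log2 0.55 and 0.78, and Vegfa, an angiogenic factor, fell with log2 -0.68. The list was not called without KO replicate 2 (adjusted p = 0.106), and the calls of Cd36, Nr1h3 and Pgk1 were lost without KO replicate 2 or WT replicate 2. Those of Slc16a3 and Vegfa were lost without WT replicate 2, where 146 of 368 calls were kept.

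**Figure D4:**
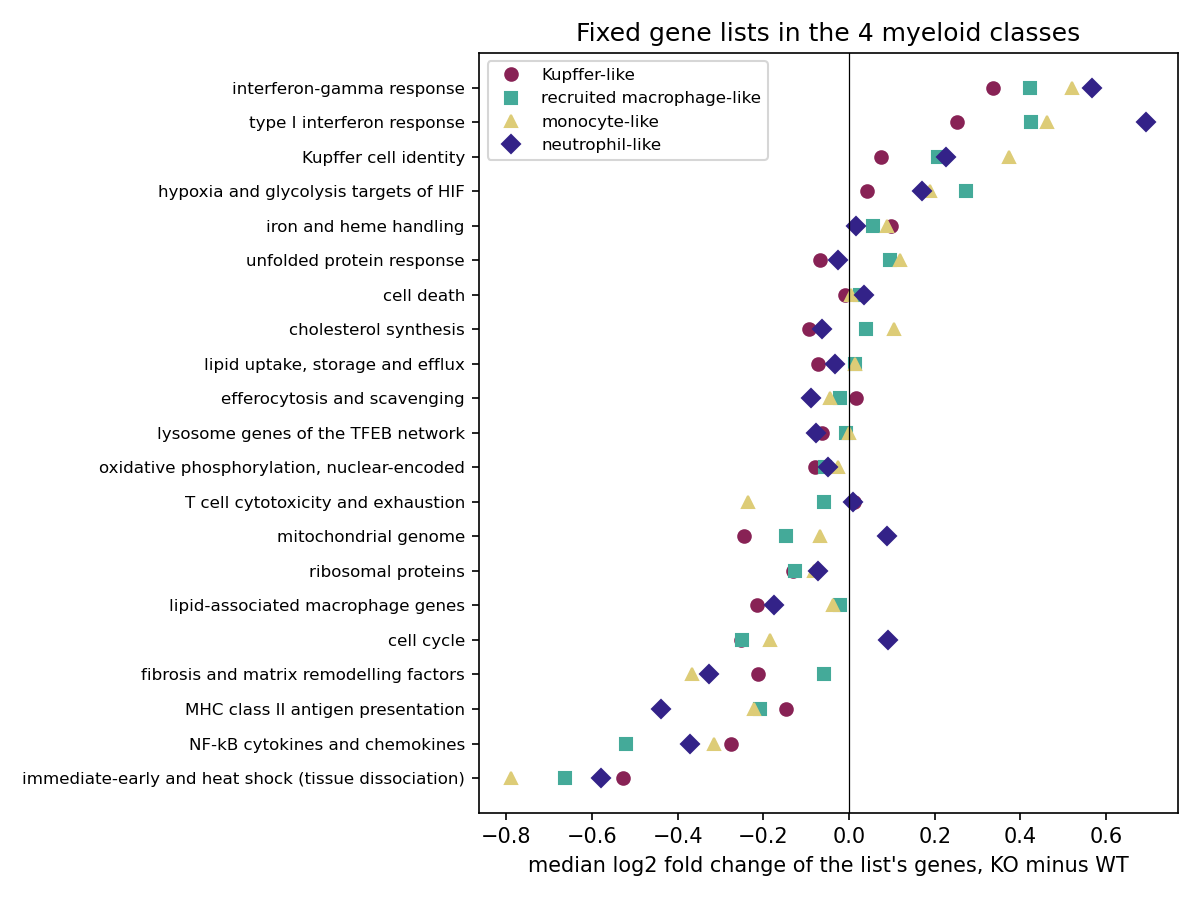
Median log2 fold change (KO minus WT) of the genes of each fixed list in the 4 myeloid classes. Of the lists plotted, the immediate-early and heat shock list lay lowest in each class, at -0.53 to -0.79, and both interferon lists lay at 0.25 to 0.69. Marker lists of other cell types are not plotted.

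In KO monocyte-like cells, Vegfa was lower. The immediate-early list was called downward and the interferon lists upward, though not with an estimated correlation. Thbs1, of the chromosome 2 window, fell by log2 2.86, from 261 and 408 CPM to 54.1 and 37.9 CPM. Vegfa fell by log2 1.77, from 39.7 and 49.3 CPM to 12.3 and 13.8 CPM, and Hilpda, a lipid droplet protein induced by hypoxia, by log2 1.31. The chemokine gene Cxcl9 rose by log2 1.41, Gbp2 and Gbp5, GTPases of the interferon-gamma response, by log2 1.62 and 1.38, and Saa3, an acute-phase protein, by log2 1.27. Cxcl9 and Gbp2 were called in 6 and 8 of the 12 classes. In all, 71 genes rose and 146 fell among 12269 tested.

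Also higher in monocyte-like cells were Gatm (log2 1.73), Wdfy1 (log2 1.33), Cfb (log2 1.29), Rasgrp1, an activator of Ras (log2 1.14), and Eif3j2 (log2 5.57). Also lower were AA467197 (log2 -2.93), Rpl29 (log2 -2.90), Eif3j1 (log2 -2.39), Grasp (log2 -1.73), Il1r2, the decoy receptor of IL-1 (log2 -1.70), Osm (log2 -1.66), Jun (log2 -1.62) and Rhob (log2 -1.58). Il1r2 was called in 10 of the 12 classes. The monocyte-like class joined clusters 9 and 11. Cluster 9 held most of it in WT replicate 1 and KO replicate 2 (60.6% and 50.3%), and cluster 11 in WT replicate 2 and KO replicate 1 (54.0% and 56.7%). At Leiden resolution 2 the class held 2009 and 2451 WT and 5304 and 5789 KO cells, against 4568 and 3518 WT and 5667 and 5847 KO cells here, and 412 genes were called, 158 of them among the 217. A cluster named recruited macrophage at that resolution held 3091 and 1214 WT and 336 and 57 KO cells. The number of called genes was 355 without KO replicate 1, 393 without KO replicate 2 and 381 without WT replicate 2, against 217 with all libraries. Without WT replicate 1 it was 178, and the calls of Cxcl9, Gbp2 and Gbp5 were lost.

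By list, 10 of 32 type I interferon genes rose in monocyte-like cells, none fell and 27 passed when adjusted over the list alone (camera adjusted p = 3.22e-31; adjusted p = 0.355 with an estimated correlation), with Ifit1 at log2 0.93 and Rsad2 at log2 0.85. Of 28 interferon-gamma genes 8 rose, none fell and 20 passed when adjusted over the list alone (camera adjusted p = 1.53e-22; adjusted p = 0.394 with an estimated correlation). Of 36 immediate-early and heat shock genes 18 fell, none rose and 26 passed when adjusted over the list alone (camera adjusted p = 1.88e-40; adjusted p = 0.318 with an estimated correlation). Of 34 NF-kB genes 7 fell, 1 rose and 17 passed when adjusted over the list alone (camera adjusted p = 2.7e-08; adjusted p = 0.297 with an estimated correlation), with the prostaglandin synthase Ptgs2 at log2 -1.08. The fibrosis and matrix list had 5 of 31 members down, none up and 14 passing when adjusted over the list alone (camera adjusted p = 6.19e-16; adjusted p = 0.297 with an estimated correlation). The hypoxia and glycolysis list was called upward with Ankrd37 at log2 0.64, although Vegfa and Hilpda fell and 13 of 36 passed when adjusted over the list alone (camera adjusted p = 0.0187; adjusted p = 0.8 with an estimated correlation). It was not called without KO replicate 2 (adjusted p = 0.281) or without WT replicate 1 (adjusted p = 0.224). The median log2 of the 11 heat shock members was -0.20 and turned to 0.29 without WT replicate 1.

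In KO neutrophil-like cells, Ptgs2 and Fosb were lower. They were called in 9 and 12 of the 12 classes, so neither change is particular to neutrophil-like cells. The MHC class II list was called downward and the interferon lists upward, though not with an estimated correlation. Ptgs2 fell by log2 1.39, from 412 and 615 CPM to 202 and 189 CPM, and Fosb by log2 1.53. The interferon-induced Gbp5, Gbp2 and Cxcl10 rose with log2 1.71, 1.69 and 1.32. The MHC class II genes H2-Eb1 and H2-Ab1, which present antigen, fell with log2 -0.64 and -0.58. In all, 79 genes rose and 103 fell among 11687 tested.

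Other genes higher in neutrophil-like cells were Eif3j2 (log2 6.72), Cfb (log2 1.56), Ly6g, a neutrophil antigen and naming marker (log2 1.66), and Klra7, Klra9 and Gzmb, genes of the unnamed cluster (log2 3.07, 2.80 and 1.33). Other genes lower were Rpl29 (log2 -3.02), Eif3j1 (log2 -2.24), Grasp (log2 -2.09), Tmem119 (log2 -1.70), Mpp7 (log2 -1.37), Olfml3 (log2 -1.36), Tnfsf9, a costimulatory ligand (log2 -1.29), and Thbs1 (log2 -1.26). Trem2 and Apoe, genes of macrophages, were also lower here (log2 -0.93 and -0.85). The class joined clusters 16, 24 and 26, and cluster 26, with Ly6g among its leading genes, held 2.75% and 3.84% of it in the WT and 4.04% and 6.95% in the KO libraries. Cluster 24 held 18.7% and 14.8% against 18.4% and 25.3%. The number of called genes was 62 without WT replicate 1, 115 without WT replicate 2, 623 without KO replicate 1 and 508 without KO replicate 2, against 182 with all libraries. The calls of Gbp2, Gbp5, Klra9, Ly6g, H2-Ab1 and H2-Eb1 were lost without either WT library. Without WT replicate 1 those of Klra7, Tmem119, Olfml3 and Apoe were lost, and without WT replicate 2 those of Cfb and Mpp7.

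In neutrophil-like cells 15 of 32 type I interferon genes rose, none fell and 27 passed when adjusted over the list alone (camera adjusted p = 1.9e-40; adjusted p = 0.244 with an estimated correlation), with Ifit1 at log2 1.25 and Oasl2 at log2 0.91. Of 28 interferon-gamma genes 8 rose, none fell and 18 passed when adjusted over the list alone (camera adjusted p = 5.33e-24; adjusted p = 0.316 with an estimated correlation). Of 16 MHC class II genes 7 fell, none rose and 12 passed when adjusted over the list alone (camera adjusted p = 8.57e-11; adjusted p = 0.327 with an estimated correlation). Of 36 immediate-early and heat shock genes 14 fell, none rose and 23 passed when adjusted over the list alone (camera adjusted p = 5.65e-33; adjusted p = 0.244 with an estimated correlation), with Atf3 at log2 -1.09 and Egr1 at log2 -0.96. The median log2 of the 11 heat shock members was -0.21 and turned to 0.15 without WT replicate 1. The hypoxia and glycolysis list was called upward, with 1 of 34 members up, none down and 10 passing when adjusted over the list alone (camera adjusted p = 0.00542; adjusted p = 0.293 with an estimated correlation), but not without KO replicate 1 (adjusted p = 0.058) or without WT replicate 1 (adjusted p = 0.0664). Markers of T or NK cells were higher, with 2 of 12 up, none down and 7 passing when adjusted over the list alone (camera adjusted p = 7.87e-09; adjusted p = 0.293 with an estimated correlation).

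MHC class II genes were lower in some other classes. The list was called downward in monocyte-like, Kupffer-like and recruited macrophage-like cells, with 1, 0 and 0 of 16 members down and 10, 0 and 3 passing when adjusted over the list alone (camera adjusted p = 0.00187, 0.0239 and 0.0381; adjusted p = 0.625, 0.577 and 0.828 with an estimated correlation). These calls were lost without KO replicate 1 (adjusted p = 0.109, 0.316 and 0.281) and without WT replicate 2 (adjusted p = 0.0681, 0.335 and 0.432). It was called downward in cDC2-like, migratory DC-like, pDC-like, B cell-like, plasma cell-like and T cell-like cells as well, with 5, 4, 1, 0, 11 and 0 of 16 down, 1 up in cDC2-like cells, and 11, 8, 8, 12, 14 and 0 passing when adjusted over the list alone (camera adjusted p = 2.95e-04, 2.46e-05, 0.00223, 2.91e-06, 5.14e-14 and 0.0331; adjusted p = 0.377, 0.382, 0.706, 0.534, 0.431 and 0.712 with an estimated correlation). Without KO replicate 1 and without WT replicate 2 the calls of pDC-like (adjusted p = 0.0775 and 0.145) and T cell-like cells (adjusted p = 0.553 and 0.36) were lost. Leaving out a library gave 0 to 3, 1 to 6, 0 to 6, 0 to 4, 5 to 10 and 0 to 3 members that fell in these 6 classes. In plasma cell-like cells 39 of 40 cell cycle genes also fell, and of 11 B or plasma cell markers 5 fell and 3 rose. The list was not called in cDC1-like or NK cell-like cells (adjusted p = 0.134 and 0.253), except in NK cell-like cells without KO replicate 2 (adjusted p = 0.0152). The cDC2-like share itself was 3.75% in the KO and 7.69% in the WT.

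Markers of other cell types also moved in the myeloid classes. In monocyte-like cells stellate cell or fibroblast markers were lower, with 1 of 8 down, none up and 5 passing when adjusted over the list alone (median log2 -1.02; camera adjusted p = 2.06e-04; adjusted p = 0.625 with an estimated correlation), a call lost without WT replicate 1 (adjusted p = 0.0772). Liver endothelial, hepatocyte and T or NK cell markers were higher, with 1 of 10, 0 of 22 and 0 of 12 up, none down, and 5, 0 and 2 passing when adjusted over the list alone (camera adjusted p = 6.79e-04, 8.39e-04 and 0.0386; adjusted p = 0.625, 0.8 and 0.8 with an estimated correlation). The hepatocyte list turned downward without KO replicate 1 (adjusted p = 0.466) and was not called without WT replicate 2 (adjusted p = 0.11). The T or NK cell list was not called without KO replicate 2 (adjusted p = 0.891) or without WT replicate 1 (adjusted p = 0.343). In Kupffer-like cells liver endothelial, hepatocyte and neutrophil markers were called upward, with 1 of 10, 0 of 22 and 1 of 9 up, 0, 1 and 1 down, and 5, 5 and 3 passing when adjusted over the list alone (camera adjusted p = 2.16e-05, 0.00216 and 0.00791; adjusted p = 0.24, 0.599 and 0.577 with an estimated correlation). The neutrophil list was not called without KO replicate 2 (adjusted p = 0.381) or without WT replicate 2 (adjusted p = 0.324). The hepatocyte list turned downward there without KO replicate 1 (adjusted p = 0.172) and was not called without WT replicate 2 (adjusted p = 0.0865). In neutrophil-like cells hepatocyte markers were called upward and stellate cell or fibroblast markers downward, with 0 of 22 and 0 of 6 called singly and 0 and 2 passing when adjusted over the list alone (camera adjusted p = 0.00183 and 0.00122; adjusted p = 0.732 and 0.327 with an estimated correlation). The first turned downward without KO replicate 1 (adjusted p = 0.0104) and the second was not called without WT replicate 1 (adjusted p = 0.516). Liver endothelial markers were called upward there, with 1 of 10 up, none down and 2 passing when adjusted over the list alone (camera adjusted p = 3.93e-04; adjusted p = 0.293 with an estimated correlation).

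Genes of the mitochondrial genome and of ribosomal proteins, which also follow RNA quality, were lower in both macrophage classes. The ribosomal list was called downward outside them too, as in migratory DC-like cells (camera adjusted p = 1.64e-06, and 0.636 with an estimated correlation). In Kupffer-like cells no member of either list was called singly or when adjusted over the list alone (camera adjusted p = 0.00524 and 1.37e-04; adjusted p = 0.577 and 0.577 with an estimated correlation), with medians of log2 -0.24 and -0.13. In recruited macrophage-like cells 1 of 13 mitochondrial genes and 0 of 54 ribosomal protein genes fell, none rose, and 2 and 0 passed when adjusted over the list alone (camera adjusted p = 0.0216 and 0.00172; adjusted p = 0.828 and 0.828 with an estimated correlation). The mitochondrial calls of Kupffer-like and recruited macrophage-like cells were lost without KO replicate 2 (adjusted p = 0.233 and 0.812) and without WT replicate 1 (adjusted p = 0.291 and 0.247), and the ribosomal call of recruited macrophage-like cells without WT replicate 2 (adjusted p = 0.432). Neither list was called in monocyte-like or neutrophil-like cells (adjusted p = 0.607 and 0.676 for the mitochondrial genome, 0.0757 and 0.0796 for ribosomal proteins). The mitochondrial list was called downward there without KO replicate 1 (adjusted p = 0.00394 and 0.00836, a turn of direction in neutrophil-like cells) and upward in neutrophil-like cells without KO replicate 2 (adjusted p = 2.92e-05), and the ribosomal list downward in monocyte-like cells without WT replicate 1 (adjusted p = 0.00688) and in neutrophil-like cells without KO replicate 2 (adjusted p = 0.00229).

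Lists on iron and heme handling, cholesterol synthesis and lipid uptake were mostly not called. Camera gave adjusted p = 0.0585, 0.388, 0.607 and 0.645 for iron and heme handling in Kupffer-like, recruited macrophage-like, monocyte-like and neutrophil-like cells, and 0.129, 0.777, 0.607 and 0.769 for cholesterol synthesis. The lipid uptake, storage and efflux list was called downward in Kupffer-like cells, with 2 of 40 members down, none up and 7 passing when adjusted over the list alone (camera adjusted p = 0.00524; adjusted p = 0.576 with an estimated correlation). That call was lost without KO replicate 2 (adjusted p = 0.0667) and without WT replicate 2 (adjusted p = 0.0865). It was not called in the other 3 classes (adjusted p = 0.847, 0.907 and 0.207), and in monocyte-like cells its median of 0.01 and its mean of -0.02 differed in sign.

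In lymphoid cells, for which the labels describe no deletion, and in dendritic cells the same core of genes differed. The labels do not say whether the myeloid-specific deletion takes in dendritic cells. Rpl29 fell by log2 2.92 to 3.04 and Eif3j2 rose by log2 4.90 to 6.27 in cDC1-like, cDC2-like, pDC-like, B cell-like, T cell-like and NK cell-like cells. Spint1, a protease inhibitor, stood at 103 and 87.6 CPM in WT and at 0 and 0.498 CPM in KO cDC2-like cells, and AA467197 fell there by log2 6.18. Il4, the cytokine of type 2 immunity, fell by log2 2.04 in T cell-like cells, from 34.97 and 27.2 CPM to 8.28 and 6.98 CPM, and Gbp2 rose by log2 2.02 in cDC1-like and 1.98 in pDC-like cells. The 8 classes together gave 1780 calls, from 26 in T cell-like to 672 in plasma cell-like cells. The plasma cell-like class held 41 and 141 cells in the WT and 211 and 885 in the KO libraries, and its count was 301 without KO replicate 1, 429 without KO replicate 2, 323 without WT replicate 2 and 265 with DESeq2. In cDC2-like cells 312 genes were called, against 66 and 31 without KO replicates 1 and 2, 76 and 105 without WT replicates 1 and 2, and 7 with no filter.

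Type I interferon genes were called upward in all 8 of these classes. In cDC1-like, cDC2-like, migratory DC-like and pDC-like cells 3 of 31 and 10, 4 and 9 of 32 members rose, none fell, and 10, 23, 11 and 26 passed when adjusted over the list alone (camera adjusted p = 1.93e-12, 1.6e-21, 8.26e-12 and 1.39e-26; adjusted p = 0.427, 0.273, 0.184 and 0.299 with an estimated correlation). In B cell-like, plasma cell-like, T cell-like and NK cell-like cells 3 of 32, 7 of 26, 0 of 32 and 7 of 32 rose, none fell, and 8, 10, 9 and 22 passed when adjusted over the list alone (camera adjusted p = 7.95e-15, 1.13e-07, 1.48e-11 and 3.21e-20; adjusted p = 0.246, 0.645, 0.635 and 0.351 with an estimated correlation). Immediate-early and heat shock genes were called downward in all 8 classes. In cDC1-like, cDC2-like, migratory DC-like and pDC-like cells 12, 16, 15 and 11 of 36 fell, none rose, and 26, 24, 28 and 23 passed when adjusted over the list alone (camera adjusted p = 1.43e-28, 2.46e-29, 2.18e-37 and 1.33e-25; adjusted p = 0.325, 0.255, 0.184 and 0.299 with an estimated correlation). In B cell-like, plasma cell-like, T cell-like and NK cell-like cells 11, 18, 5 and 20 of 36 fell, 1 rose in plasma cell-like cells, and 24, 25, 21 and 24 passed when adjusted over the list alone (camera adjusted p = 8.39e-34, 9.93e-15, 3.02e-28 and 5.84e-34; adjusted p = 0.19, 0.431, 0.445 and 0.165 with an estimated correlation). NK cell-like cells joined clusters 21, 22 and 28. Cluster 22 held 70.9% and 73.6% in the WT and 59.6% and 62.6% in the KO libraries. Cluster 28 held 9.28% and 13.8% against 27.8% and 18.8%. Cluster 21 held 19.8% and 12.6% against 12.6% and 18.6%, and its NK cell score of 1.02 lay near 0.928 for recruited macrophages. Its cells held a median of 4120 UMIs, against 1484 in cluster 22, so macrophage RNA in this part of the class is not excluded. T cell-like cells joined clusters 0 and 2, of which cluster 2 held 68.7% and 57.2% in the WT and 79.0% and 50.4% in the KO libraries. In T cell-like cells 9 genes were called without WT replicate 1, 374 without KO replicate 1, 304 without KO replicate 2 and 43 without WT replicate 2, against 26 with all libraries. Of 1421 genes called in at least 1 of the 12 classes, 94 were called in at least 6, and 93 of these in 1 direction.

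Markers of other cell types moved in these lymphoid and dendritic classes too. T or NK cell markers were called upward in cDC1-like, cDC2-like, migratory DC-like, pDC-like, B cell-like and plasma cell-like cells, with 1 of 10 and 0, 1, 4, 2 and 4 of 12 up, none down, and 5, 6, 1, 9, 7 and 8 passing when adjusted over the list alone (camera adjusted p = 1.69e-08, 1.63e-04, 1.24e-04, 1.99e-13, 1.35e-11 and 5.54e-07; adjusted p = 0.325, 0.377, 0.382, 0.299, 0.279 and 0.497 with an estimated correlation). Liver endothelial markers were called upward in cDC1-like, cDC2-like, migratory DC-like, pDC-like, plasma cell-like, T cell-like and NK cell-like cells, with 1, 3, 0, 1, 3, 0 and 0 up, none down, and 3, 6, 2, 4, 6, 4 and 3 of 10 (8 in plasma cell-like cells) passing when adjusted over the list alone (camera adjusted p = 1.07e-05, 4.91e-07, 1.35e-04, 1.28e-04, 0.00228, 1.07e-05 and 0.00221; adjusted p = 0.325, 0.255, 0.337, 0.32, 0.645, 0.445 and 0.351 with an estimated correlation). In B cell-like cells the list was called only without WT replicate 1 (adjusted p = 0.0115).

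Hepatocyte markers were called upward in all 8 classes. In cDC1-like, cDC2-like, migratory DC-like and pDC-like cells 1, 1, 2 and 1 of 22 rose, 1 fell in pDC-like cells, and 12, 3, 11 and 5 passed when adjusted over the list alone (camera adjusted p = 7.11e-12, 1.14e-07, 2.35e-12 and 0.00224; adjusted p = 0.439, 0.446, 0.382 and 0.706 with an estimated correlation). In B cell-like, plasma cell-like, T cell-like and NK cell-like cells 0 of 22, 0 of 18, 0 of 22 and 1 of 22 rose, none fell, and 1, 5, 0 and 5 passed when adjusted over the list alone (camera adjusted p = 0.0346, 2.97e-05, 3.67e-07 and 2.68e-08; adjusted p = 0.781, 0.729, 0.712 and 0.529 with an estimated correlation). Without KO replicate 1 the calls of cDC1-like, cDC2-like, pDC-like, T cell-like and NK cell-like cells were lost (adjusted p = 0.18, 0.381, 0.657, 0.79 and 0.414), and the B cell-like list turned downward (adjusted p = 9.85e-04). That of pDC-like cells was also lost without WT replicate 1 (adjusted p = 0.202) and that of B cell-like cells without WT replicate 2 (adjusted p = 0.879).

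Further marker lists were called in some of these classes. B or plasma cell markers were called upward in cDC1-like and cDC2-like cells, with 1 of 9 and 0 of 10 up, none down, and 3 and 3 passing when adjusted over the list alone (camera adjusted p = 0.00367 and 0.0139; adjusted p = 0.504 and 0.606 with an estimated correlation). Both calls were lost without WT replicate 1 (adjusted p = 0.355 and 0.417), and that of cDC2-like cells without KO replicate 2 (adjusted p = 0.239). Neutrophil markers were called downward in B cell-like and cDC2-like cells, with 1 and 1 of 7 down and none up. In cDC2-like cells their median of log2 0.29 and their mean of -0.12 differed in sign. Adjusted over the list alone 2 and 1 members passed, and camera made both calls (adjusted p = 0.0268 and 0.00724, against 0.598 and 0.273 with an estimated correlation). Both were lost without WT replicate 1 (adjusted p = 0.085 and 0.051), that of B cell-like cells without KO replicate 1 (adjusted p = 0.92), and that of cDC2-like cells without WT replicate 2 (adjusted p = 0.077), and it turned upward without KO replicate 1 (adjusted p = 0.41). Stellate cell or fibroblast markers were called downward in T cell-like and cDC2-like cells, with 0 of 9 and 1 of 5 down, none up, and 2 and 2 passing when adjusted over the list alone (camera adjusted p = 0.00673 and 0.00871; adjusted p = 0.712 and 0.378 with an estimated correlation). These were lost without WT replicate 1 in T cell-like (adjusted p = 0.206) and without KO replicate 1 in cDC2-like cells (adjusted p = 0.0793).

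The last comparison asked whether the KO effect differed between resident and recruited macrophages. Gpnmb, Mmp12, Cd63, Fabp5 and Apoc1, which fell in Kupffer-like cells, were relatively higher in the KO effect of recruited macrophage-like cells, by log2 0.77, 0.76, 0.41, 0.43 and 0.57. Cd9 fell in both classes (log2 -0.93 and -0.73), and no gene list was tested on the difference. The KO effect on Clec4f, a naming marker of Kupffer-like cells, was higher in recruited macrophage-like cells too, by log2 0.64. Cd36 differed by log2 0.61, at -0.16 in Kupffer-like and 0.45 in recruited macrophage-like cells. Gatm, of the chromosome 2 window, and C4b rose more in Kupffer-like cells, with differences of log2 -0.59 and -0.70. In the edgeR interaction test with library as block, 256 of 12866 genes differed, 165 with a higher and 91 with a lower KO effect in recruited macrophage-like cells. The number was 45 without WT replicate 2. Without the block no gene passed in edgeR, and 502 had an unadjusted p under 0.05.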

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

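All tests on RNA from other cells, genome segments, handling, library mixing and allele number in this part were chosen after the result was seen, while the interaction test was planned.

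The KO effect differed between recruited macrophage-like and Kupffer-like cells for 22 named genes by the edgeR interaction test. On the log2 scale, recruited minus Kupffer, it was higher for Gpnmb (0.77), Mmp12 (0.76), Gbp2 (0.76), Gdf15 (0.72), Cd36 (0.61), Apoc1 (0.57), Ly6c2 (0.56), Atf3 (0.55), Plk2 (0.47), Fabp5 (0.43), Cd63 (0.41), Pgk1 (0.40), Nr1h3 (0.37) and Ifi47 (0.35). It was lower for Il1r2 (-0.96), Lyz2 (-0.72), C4b (-0.70), Pmepa1 (-0.69), Gatm (-0.59), Nfkbiz (-0.46), Cxcl2 (-0.37) and Ccl5 (-0.33). Without the block no gene passed in edgeR, 502 having an unadjusted p under 0.05.

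The first pattern was that genes changed alike in most cell classes: 94 genes were called in at least 6 of 12 classes, among them Rpl29 and Eif3j1 in all 12. The deletion acting in myeloid cells alone is argued against: of 111 genes called in at least 3 myeloid classes 110 were tested in T cell-like cells, and the 52 that T cell-like cells held at 0.5 or more of the myeloid level had there a median of 0.696 of their myeloid change, the lowest of T, NK and B cell-like cells, although 11 of the 110 were called. RNA from other cells stays open, since 61.0% of the calls inside the densest window and 64.1% outside it fell in classes above 0.220 of the highest class level, the highest that Lyz2 reached as free RNA in T, NK and B cell-like cells, and genes such as Igha, Clec4f and Gzmb are among the 94. Of the 94 genes, 9 lay within 118111876 to 127522094 of chromosome 2, as dense a window of 10 Mb as in 0.0003 of 100000 random draws, so genome segments carried by the KO libraries may account for these 9 (Thbs1, Spint1, Chp1, Jmjd7, Eif3j1, Gatm, AA467197, Dusp2 and Kcnip3). Only the densest window was tested. Among the other 85, Dusp7, Rpl29 and Mapkapk3 lie between 106368632 and 107289877 of chromosome 9 and fell, with medians of log2 -1.24, -3.00 and -0.67 over the classes where called. What the other 85 share, and any biological effect on cells outside the deletion, stays open.

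The second pattern was lower immediate-early and heat shock genes in the KO. Immediate-early genes were lower in T, NK and B cell-like cells too, with medians of -0.66 log2 or lower, so handling of the libraries may account for them. The library WT replicate 1 alone is argued against for immediate-early genes, which kept at least 0.867 of their median in all 4 myeloid classes without it. For heat shock genes the ratio fell as low as -1.45, a turn of sign, so that library may account for these. An effect of the deletion on immediate-early genes was not separated from handling and stays open.

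The third pattern was the unequal loss of Lyz2. In KO replicate 1 Lyz2 stood at a median of 0.519 of the WT mean over 12 classes (0.385 to 0.611), and in KO replicate 2 at 0.00426. Cells with the Rpl29 level of the WT libraries, mixed into KO replicate 1, are argued against, since Rpl29 would need only 0.372% of them. Rpl29 was called in all 12 classes, so mixed-in cells low in Rpl29 that keep Lyz2 would go unseen. Reads assigned to Lyz1 are argued against, since its gain was 2.45% of the loss. An allele that ends Lyz2 transcription, in 1 copy in KO replicate 1 and 2 copies in KO replicate 2, may account for the values, and the labels give no genotype at this locus.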

How the results depend on the processing

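The settings with 1 cluster of a class alone, clustering without called genes and cluster numbers in place of classes were chosen after the result was seen; the others were planned. In planned settings other than leaving out a library, 2251 values of named genes lay on the same side of the threshold and 86 were no longer past it. These settings kept the direction of named genes called there or in the main setting. Leaving out a library kept it too, with 723 values on the same side and 109 no longer past it. Genes called in neither setting were not checked for direction. Epas1 and Lyz2 in the myeloid classes were not among these values and are given below. Epas1, which was not called, changed sign in Kupffer-like and neutrophil-like cells when a library was left out. The cause of the changes below was not tested, except that leaving out a library or a cluster lowers the number of samples or cells.

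Called genes in Kupffer-like cells were 26 in cluster 25 alone, 48 in cluster 6 alone, 302 with genes of other cells left out, 998 with no filter and 684 with the replicate block. In recruited macrophage-like cells they were 899 with no filter and 1131 with the block. In monocyte-like cells they were 412 at Leiden resolution 2, 143 with equal cells per library, 339 with genes of other cells left out and 340 with the block. In neutrophil-like cells they were 306 at 1000 UMIs or more, 59 and 5 in clusters 24 and 26 alone, 103 with doublets at the nominal rate, 292 with genes of other cells left out, 748 with no filter and 716 with the block. In the lymphoid and dendritic classes they were 1023 with DESeq2, 4299 with no filter and 3502 with the block.

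Shares past the test were 3 at Leiden resolution 2 and 1 with the block (plasma cell-like, 2.30). The 3 were cDC2-like, ILC2-like (log2 -2.22) and an unnamed cluster of Ly49 genes (log2 5.34). That cluster scored highest for monocytes and held a median of 4108 UMIs, against 1234 in the unnamed cluster at resolution 1. The cluster with the same leading genes as the latter was named NK cell at resolution 2, with a median of 1233 UMIs. It did not pass on its own (log2 4.56, edgeR adjusted p = 0.0624). The monocyte-like share moved from log2 0.31 to 1.10 at Leiden resolution 2 and did not pass (adjusted p = 0.0625). The Kupffer-like share passed with a gate per cell (log2 0.90) and over macrophage-like and monocyte-like cells (0.68), as did the recruited macrophage-like share over the latter (-0.88). The gate took cells with at least 3 of Clec4f, Vsig4, Timd4, Cd5l, Marco, Folr2, C6 and Fcna. Clec4f, Marco, Vsig4 and Cd5l were called in 9, 6, 6 and 6 classes, with medians of log2 0.83, 2.35, 0.80 and 0.80 there. More marker RNA in other cells was thus not separated from more Kupffer-like cells in the gate. In the 4 myeloid classes, called lists were 0 with an estimated correlation and 2 with fry. The interaction gave 395 genes with no doublets removed and 0 without the block. Lyz2 passed with no filter and with the block in Kupffer-like (log2 -2.10 and -3.95), neutrophil-like (-2.13 and -4.20) and recruited macrophage-like cells (-2.44 and -5.11).

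Leaving out a library gave 91 to 535 genes in Kupffer-like, 160 to 392 in recruited macrophage-like, 178 to 393 in monocyte-like and 62 to 623 in neutrophil-like cells, 1556 to 2638 in the lymphoid and dendritic classes, 45 to 254 for the interaction and 51 to 64 called lists. Log2 shares ranged from 0.56 to 1.04 (Kupffer-like) and from -1.06 to -0.51 (recruited macrophage-like). Lyz2 ranged from -6.93 to -1.13, -9.51 to -1.44, -8.88 to -1.02 and -7.61 to -1.15, and Epas1 from -0.16 to 0.39, 0.07 to 0.31, 0.15 to 0.36 and -0.14 to 0.41, in Kupffer-like, recruited macrophage-like, monocyte-like and neutrophil-like cells.

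In the myeloid classes, directions turned without KO replicate 1 for 7 lists. Each is given with the adjusted p without that library and at the other end of the range over left-out libraries. They were hepatocyte markers in Kupffer-like (0.172, 3.38e-34), monocyte-like (0.466, 2.21e-28) and neutrophil-like cells (0.0104, 4.41e-28), neutrophil markers in recruited macrophage-like (4.23e-05, 0.802) and monocyte-like cells (0.0111, 0.835) and B or plasma cell markers in monocyte-like cells (0.00042, 0.971, and 2.67e-06 with the replicate block). The last was the mitochondrial genome in neutrophil-like cells (0.00836, from 2.92e-05 to 0.748). In neutrophil-like cluster 26 alone Apoe, Cd86 and Osm turned to log2 0.37, 0.18 and 0.0013.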

Other observations

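The tests on clones and on finer clusters in this part were chosen after the result was seen.

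At Leiden resolution 2 a monocyte-like cluster with Cxcl10, Cxcl9 and Ifit1, genes of the interferon response, differed in share of CD45+ cells, with log2 2.17 (edgeR adjusted p = 0.0374). These 3 genes rose in KO monocyte-like cells, so the share and that change are not separate results. More such cells and higher expression were not told apart. An ILC2-like cluster, lymphoid cells of type 2 immunity, differed with log2 -2.22 (adjusted p = 0.0287). A recruited macrophage-like cluster with Thbs1, Hspa1a and Osm held 8.65% and 3.71% of WT and 0.867% and 0.142% of KO cells. It did not pass (log2 -3.61, edgeR adjusted p = 0.14). These 3 genes fell in KO recruited macrophage-like cells, and Thbs1 and Osm in KO monocyte-like cells too. This share and these falls are thus not separate results. Fewer such cells and lower expression were not told apart.

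The unnamed cluster of Ly49 genes at resolution 1 held 189 UMIs of T cell receptor Trbv segments in KO replicate 1, of which Trbv3 made up 89.4%. In KO replicate 2 it held 33, of which Trbv29 made up 36.4%. An expansion of 1 T cell clone would give such a leading segment in KO replicate 1, where the cluster held 4821 cells. T cell-like cluster 0 also held most of its Trbv UMIs in 1 segment, Trbv2, in WT replicate 2 (54.8%) and KO replicate 2 (58.2%). A leading segment thus does not single out a clone, and a clone in KO replicate 1 stays open. In KO replicate 2 a clone cannot be told apart from a mixed population, since the UMIs are few and no segment holds most of them.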
